A study of Mus musculus with 9 samples.

How the data were processed

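RNA was measured by bulk sequencing in 9 libraries from mouse ventral hippocampus, 3 in each of 3 groups named in the labels as CRS-WT, CRS-WT-DR5-12D and CRS-NKAα1+/-. Per the labels, total RNA was extracted with TRIzol, its integrity was read on a Bioanalyzer, and library fragments were selected by size. The labels do not state which animal each library came from, so the p values below measure the spread between these samples, which may in part be technical.

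The authors deposited 1 table of FPKM (fragments scaled to the length of the gene model and to the depth of the library) with 53465 genes and 9 columns, each of which was mapped to a library by its name. The labels name cutadapt, HISAT2 and RSEM 1.2.30 with the build GRCm38. The annotation release, the strandedness and any filter are not given in the sources used here, so antisense and overlapping genes carry an added doubt about which transcript their fragments came from. Gene positions, exon lengths and GC content were taken here from GENCODE vM21 on GRCm38, which holds 53274 of the 53465 identifiers. A symbol is shared by more than 1 identifier in 110 cases, and identifiers were used throughout.

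The table was checked for what it holds. In 16207 of the 17753 tested genes the FPKM values were whole fragment counts divided by the merged exon length of the gene and by 1 number per library, within a tolerance of 0.02 of a whole count, and in the other 1546 they were so at another whole-number length. That number implies depths of 15117452 to 27323380 fragments per library, and the recovered counts sum to 14869354 to 27212653. The ratio of the implied to the recovered depth runs from 0.963 to 1.04, so a scaling between libraries appears to be part of the deposited values. No 2 columns are identical, and Pearson r of log2 values between pairs of libraries lies between 0.950 and 0.986.

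Genes with a mean FPKM of at least 0.5 over the 9 libraries were kept, 17753 of 35485 genes above 0 in at least 1 library. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with all 9 libraries in 1 fit, group means only and a trend of the spread on the mean. Each of the 3 pairs of groups was compared with two-sided moderated tests, and a moderated F-test asked for any difference among the 3 groups. Benjamini-Hochberg adjustment was made over all genes tested, with calls at an adjusted p under 0.05. Log2 fold changes of this fit are differences of group means of log2(FPKM + 1), given with their standard error. The added 1 shrinks them for genes with low values, so they can lie well below the log2 ratio of the FPKM means. FPKM is given as mean ± SD of 3 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the tables and plots.

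Tested on simulated data with the spread of these libraries, the fit recovered 47%, 58% and 54% of genes changed 2-fold in CRS-NKAα1+/- against CRS-WT, CRS-WT-DR5-12D against CRS-WT and CRS-WT-DR5-12D against CRS-NKAα1+/-. Of genes changed 4-fold it recovered 79%, 78% and 75%. False calls made up 3.82%, 4.90% and 9.15% of all calls, and the last share lies above the nominal 5%, a result that was not explained.

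Before the data were examined, 40 gene lists were fixed, covering cell types, hippocampal subfields and neighbouring regions, immune and stress responses, synaptic genes, ion pumps, mitochondrial and ribosomal genes. Each was tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 40 lists within a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether the genes of a list move on balance 1 way. Members were also adjusted over the list alone. With an estimated correlation camera called 0 lists in each comparison, the lowest adjusted p being 0.551, 0.672 and 0.181 for the comparisons in the order above, where the preset correlation called 12, 16 and 11. Fry called 0, 0 and 4.

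The rule for naming genes was also fixed in advance. In each comparison up to 10 genes that rose and 10 that fell are named, by the largest change among those with an adjusted p under 0.05, a mean FPKM of at least 1 and no overlap between the 2 groups. Genes known only by a Gm or Rik number were left out, and each direction with fewer than 5 was filled to 5 by the smallest unadjusted p. Atp1b1 is always named, as are up to 4 members with the smallest p of each list that was called or has members past the threshold. Results for some genes that the rule names are not reported here, with no others put in their place. Genes named outside the rule are marked as chosen after their values were seen. The sex-linked Ddx3y and Xist and the miRNA model Gm23935 are also outside it. Of 201 named or called genes, 73 share exon bases with another annotated gene and 36 share at least 10% of them. Not all of these are marked below.

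The 11 alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean FPKM of at least 2, rescaling to TPM, median-of-ratios and quantile scaling, a fit of 2 groups only, no trend, robust fitting, array weights and a block on the replicate number, besides omission of each of the 9 libraries. A further 4 were chosen after seeing the data: omission of 3 libraries with low dentate gyrus genes, the mean of the dentate gyrus list as a covariate, voom on recovered counts, and the first residual component as a covariate. Other splits of the libraries were counted in full for each pair of groups (10 splits) and by 100 drawn from the 280 splits into 3 groups. For the relation between the changes against CRS-WT, all 840 regroupings of the 9 libraries and all 60 of the 6 without the 3 libraries with low dentate gyrus genes were counted. No library was left out of the values given first.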

Results

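Gene expression was measured in freshly taken mouse ventral hippocampus in 9 libraries. The groups CRS-WT, CRS-WT-DR5-12D and CRS-NKAα1+/- had 3 libraries each. The mark +/- denotes 1 intact copy, and the labels spell out neither CRS nor DR5-12D. The depth implied by the deposited values was 27323380, 15117452 and 21688556 fragments in CRS-WT replicates 1 to 3. It was 15656850, 22648992 and 26195300 in CRS-NKAα1+/- and 26215039, 18989002 and 16308415 in CRS-WT-DR5-12D.

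Transcripts of dentate gyrus granule cells were lower in 3 of the 9 libraries, CRS-NKAα1+/- replicates 1 and 2 and CRS-WT-DR5-12D replicate 1. The mean of the 16 listed granule cell genes on the log2 scale was 1.61, 1.52 and 1.58 there and 2.46 to 2.79 in the other 6, and the median difference over the genes was −0.839. Some members changed far less than others, such as Calb1, with 1659, 1845 and 2619 fragments in the 3 and 1527 to 2869 in all 9. C1ql2, a synaptic organizer of granule cells, stood at 0.926, 0.596 and 0.973 FPKM in these samples and at 23.6 to 40.1 in the other 6. Prox1, the transcription factor that sets granule cell identity, stood at 1.28, 0.9 and 1 FPKM against 7.51 to 11.6. In the same 3 samples Lamp5, a membrane protein of forebrain neurons, reached 94.9, 97.2 and 64.5 FPKM against 12.2 to 15.9. Arc, an activity-induced synaptic gene, stood at 62.8, 66.2 and 118 FPKM against 20.8 to 41.6. These genes were chosen after their values were seen. The first principal component, with 41.7% of the variance, placed the 3 samples at 30.1 to 36.6 and the other 6 at −21.8 to −12.2. Other lists split the same way. In the same 3 samples list means were lower for CA3 genes (2.88 to 2.89 against 3.32 to 3.51) and CA2 genes (2.676 to 2.685 against 2.96 to 3.09). They were also lower for ependymal (1.43 to 1.60 against 2.12 to 2.68) and choroid plexus genes (0.315 to 0.46 against 0.823 to 1.525). Means of CA1 genes overlapped, and those of pan-neuronal genes were higher (6.51 to 6.61 against 6.28 to 6.42).

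**Figure D1:**
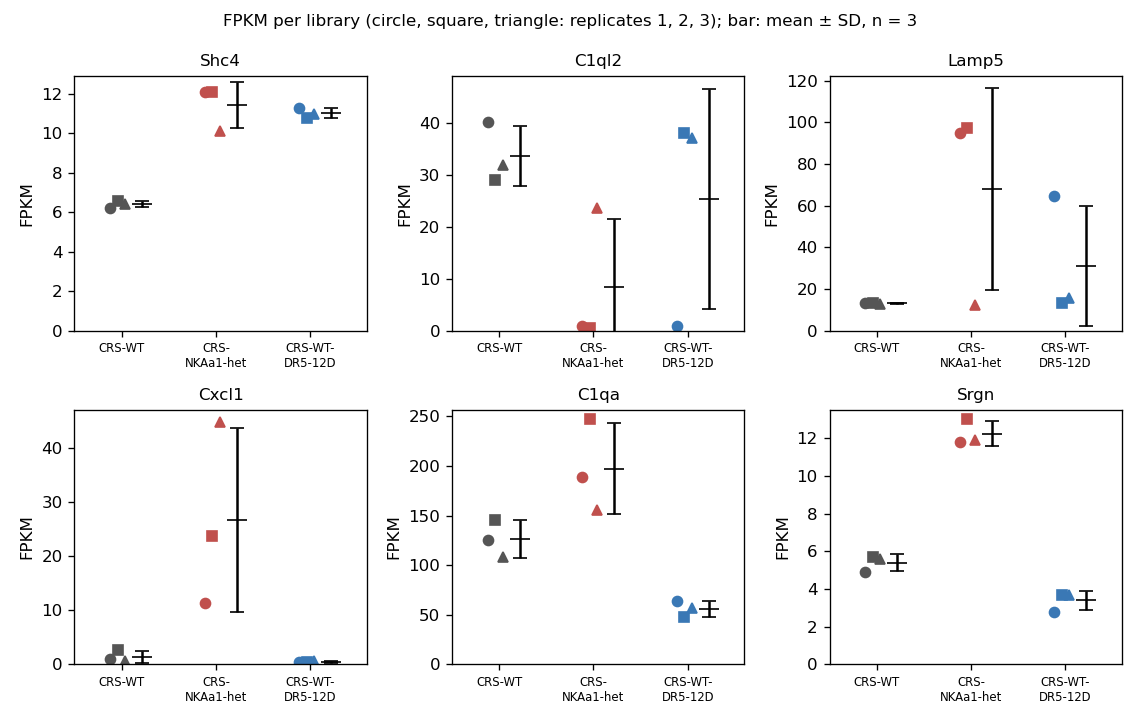
FPKM of Shc4, C1ql2, Lamp5, Cxcl1, C1qa and Srgn in each of the 9 libraries by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). C1ql2 lies below 1 in CRS-NKAα1+/- replicates 1 and 2 and CRS-WT-DR5-12D replicate 1, while Srgn lies between 11.8 and 13 in CRS-NKAα1+/- and between 2.80 and 3.69 in CRS-WT-DR5-12D.

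The first comparison asks how the hippocampus of CRS-NKAα1+/- differs from that of CRS-WT. The list of Na,K-ATPase subunits and partners, the pump that keeps the sodium and potassium gradients of cells, was not called (median −0.020, mean 0.073, camera adjusted p 0.911). Of its members Fxyd5 was higher by 0.72 and Fxyd1, −0.60, lower, both past the threshold adjusted over the list alone. Both were named after their values were seen. Atp1b1, named in advance, had a log2 fold change of −0.17 ± 0.15, not past the threshold, and its sign turned under some settings. Of its exon bases 18.7% overlap Nme7.

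Among all genes, 4 rose and 0 fell in CRS-NKAα1+/- against CRS-WT, 3 of them protein-coding and 2 of these known from immune cells. Srgn, which encodes the granule proteoglycan serglycin (ENSMUSG00000020077, chromosome 10, 62493833 to 62527451), rose from 5.40 ± 0.435 to 12.2 ± 0.667 FPKM, a log2 fold change of 1.05 ± 0.10. C5ar1, the receptor for complement fragment C5a (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540), rose from 0.465 ± 0.0509 to 3.71 ± 1.04 FPKM. The change was 1.66 ± 0.17 on the log2(FPKM + 1) scale, which shrinks changes of low values. Shc4, a signalling adaptor (ENSMUSG00000035109, chromosome 2, 125627447 to 125724148), rose from 6.40 ± 0.157 to 11.4 ± 1.18 FPKM, by 0.75 ± 0.078. The fourth, the antisense RNA Gm43701, rose by 2.23 ± 0.23 and was named after its values were seen. All 4 had a limma adjusted p of 0.0366 and were higher in 3 of 3 libraries than in any CRS-WT library. Next came Csf3, a granulocyte growth factor, at 1.96 ± 0.24 (adjusted p 0.0568), with between 0 and 9 fragments per CRS-WT library, and CT030161.2 at 1.16 (adjusted p 0.0595), neither past the threshold. Of genes with lower values, those named by the smallest unadjusted p also missed it. Among them were Plpp3, a lipid phosphatase of astrocytes, at −0.62 (adjusted p 0.0525), Ltc4s, leukotriene C4 synthase, at −0.91 (0.0694), AC123061.2 at −0.74 (0.0866), Gpr17, a receptor of maturing oligodendrocyte precursors, at −0.87 (0.0866) and Asrgl1 at −0.60 (0.0916). At an unadjusted p under 0.05 there were 2504 genes, and in 20.9% of genes the 2 groups did not overlap, where chance gives 10% on average. Genes move together, so a single grouping can lie far from 10%, and the share in other splits was not counted. Limma called 0 genes without CRS-WT replicate 1 or 2, CRS-NKAα1+/- replicate 2, or CRS-WT-DR5-12D replicate 2 or 3 (1533, 1729, 1300, 2372 and 2329 at an unadjusted p under 0.05), 2 without CRS-WT replicate 3 or CRS-WT-DR5-12D replicate 1, 22 without CRS-NKAα1+/- replicate 1 and 25 without replicate 3. It called 0 with no filter on low values (3538 at an unadjusted p under 0.05). Omission of the 3 samples with lower dentate gyrus transcripts leaves CRS-NKAα1+/- replicate 3 alone in its group, so no count is given here. After rescaling to TPM it called 98 higher and 7353 lower, where the median of all genes moved from 0.0091 to −0.42.

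Immune and glucocorticoid-responsive lists were higher in CRS-NKAα1+/- than in CRS-WT as sets, although 0 of their members passed over all genes. Interferon-response genes had a median log2 fold change of 0.64, with 18 of 18 higher and 3 past the threshold adjusted over the list alone (camera adjusted p 1.32e-07; adjusted p = 0.551 with an estimated correlation). Examples are the antiviral effector Ifit1 at 1.14 ± 0.21, the transcription factors Irf9 at 0.71 and Irf7 at 1.64, and Rtp4 at 1.03, 13.9% of whose exon bases overlap another gene. Inflammasome and cytokine genes had a median of 0.515, with 18 of 22 higher and 7 past the threshold adjusted over the list alone (camera adjusted p 4.78e-06; adjusted p = 0.551 with an estimated correlation). Among them the cytokine Il1b was at 3.34 ± 0.58, from 0.754 ± 0.496 to 21.7 ± 17.9 FPKM, Tnf at 2.61 with 2 to 9 fragments per CRS-WT library, Il1a at 2.05 and the adaptor Myd88 at 0.35, which turned to −0.038 under TPM. The glucocorticoid list had a median of 0.38, with 17 of 20 higher and 5 past the threshold adjusted over the list alone (camera adjusted p 1.1e-05; adjusted p = 0.551 with an estimated correlation). Its members with the smallest p were the cell-cycle inhibitor Cdkn1a at 2.09 ± 0.43, the NF-kappaB inhibitor Nfkbia at 1.29, Arrdc2 at 0.63 and the lipid droplet protein Plin4 at 0.88. Antigen presentation and complement genes had a median of 0.44, with 15 of 17 higher and 0 past the threshold adjusted over the list alone (camera adjusted p 0.00225; adjusted p = 0.61 with an estimated correlation). Examples are the complement chains C1qa at 0.62, C1qb at 0.61 and C1qc at 0.57 and the immunoproteasome subunit Psmb8 at 0.83. That call was lost without CRS-NKAα1+/- replicate 3 (adjusted p 0.116), and the mean of the antigen presentation list was lower in CRS-NKAα1+/- replicate 1 (3.27) than in any CRS-WT library (3.39 to 3.6), with 4.29 and 4.135 in replicates 2 and 3. The interferon list mean was 1.98 in replicate 1 beside 3.13 and 2.25, with 1.64 to 1.91 in CRS-WT, and the inflammasome list mean 1.75 beside 2.47 and 3.05, with 1.38 to 1.62 in CRS-WT. Without CRS-NKAα1+/- replicate 2 the medians of the interferon and antigen presentation lists were 0.285 and 0.16. Under TPM the medians were 0.33, 0.18, −0.024 and 0.055 in the order given, all above the shift of all genes.

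Oligodendrocyte, vascular, red blood cell and granule cell lists were lower in CRS-NKAα1+/- than in CRS-WT as sets, again with 0 members past the threshold over all genes. Oligodendrocyte and myelin genes had a median of −0.59, with 16 of 18 lower and 4 past the threshold adjusted over the list alone (camera adjusted p 3.56e-07; adjusted p = 0.551 with an estimated correlation). They include the myelin protein Opalin at −1.09 ± 0.21, Cnp at −0.68 and Trf at −0.63. Of 10 precursor genes 5 were lower adjusted over the list alone (median −0.36, camera adjusted p 0.00016; adjusted p = 0.551 with an estimated correlation), with Bmp4 at −1.08, Gpr17 at −0.87, Enpp6 at −0.65 and Sox10 at −0.54. Endothelial genes had a median of −0.28, with 5 of 12 lower adjusted over the list alone (camera adjusted p 0.000416; adjusted p = 0.551 with an estimated correlation). Among them were the receptors Flt1 at −0.60 and Tek at −0.38, Itm2a at −1.30 and the monocarboxylate transporter Slc16a1 at −0.58. Mural cell genes had a median of −0.32 with 1 of 9 lower adjusted over the list alone (camera adjusted p 0.00369; adjusted p = 0.551 with an estimated correlation), Rgs5 at −0.90, beside Vtn at −0.48, Pdgfrb at −0.32 and Tagln at −0.44. Red blood cell genes had a median of −1.68, with 6 of 6 lower and 5 past the threshold adjusted over the list alone (camera adjusted p 1.39e-05; adjusted p = 0.551 with an estimated correlation). Members include the globins Hbb-bt at −2.02, Hba-a1 at −2.07 and Hba-a2 at −1.91 and the haem enzyme Alas2 at −0.65. The pairs of globin genes are near copies of each other, so their separate values are uncertain. Of the exon bases of Trf 63.5% also belong to Gm20425, and of those of Tagln 62.4% lie opposite exons of Gm48529. Without the 3 samples with lower dentate gyrus transcripts CRS-NKAα1+/- replicate 3 is alone in its group. The medians of the myelin, precursor, endothelial, mural and red blood cell lists were then −0.40, −0.15, −0.31, −0.26 and −1.85. With the dentate gyrus covariate they were −0.27, −0.13, −0.23, −0.12 and −1.53, and the mural call was lost (adjusted p 0.0617).

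Granule cell genes had a median of −0.66 in CRS-NKAα1+/- against CRS-WT, with 14 of 16 lower and 0 past the threshold adjusted over the list alone (camera adjusted p 0.000241; adjusted p = 0.551 with an estimated correlation). Examples are Dsp at −1.32, Lct at −1.53, Plk5 at −0.73 and Sipa1l2 at −0.56. The list mean was 1.61 and 1.52 in CRS-NKAα1+/- replicates 1 and 2 and 2.46 in replicate 3, beside 2.48 to 2.79 in CRS-WT. Neurogenesis and cell-cycle genes had a median of −0.375 with 1 of 10 lower adjusted over the list alone (camera adjusted p 0.0327; adjusted p = 0.61 with an estimated correlation), the transcription factor Sox4 at −0.42, beside Sox11 at −0.42, Tubb2b at −0.83 and the neuroblast gene Dcx at 0.29. Meningeal fibroblast and matrix genes had a median of −0.30 with 0 of 11 past the threshold adjusted over the list alone (camera adjusted p 0.0294; adjusted p = 0.61 with an estimated correlation). Examples are the collagens Col1a1 at −1.26 and Col3a1 at −0.69, Ogn at −0.71 and Fmod at −0.66. Of the exon bases of Sox4, the neurogenesis gene past the list threshold, 54.6% lie opposite exons of Gm26735. The neurogenesis call was lost without CRS-WT replicate 1 or CRS-NKAα1+/- replicate 1 (adjusted p 0.272 and 0.164), and the meningeal call without CRS-WT replicate 1 or CRS-NKAα1+/- replicate 1 or 2 (0.272, 0.0548 and 0.101). Without the 3 samples with lower dentate gyrus transcripts, where CRS-NKAα1+/- replicate 3 is alone in its group, the medians of the granule cell, neurogenesis and meningeal lists were −0.13, 0.086 and −0.0013. The dentate gyrus covariate ended all 3 calls (0.917, 0.863 and 0.0617). For the granule cell list this was fixed in advance, because the covariate is the mean of that list. The meningeal median was −0.17 without CRS-WT replicate 1 and −0.46 without CRS-NKAα1+/- replicate 3. With voom it was −0.78, and the call held (camera adjusted p 0.0298). After rescaling to TPM the endothelial, mural, meningeal, granule cell and neurogenesis calls were lost (adjusted p 0.0733, 0.173, 0.978, 0.408 and 0.989). Quantile scaling ended the meningeal and neurogenesis calls (0.0511 and 0.0653), and a mean FPKM of at least 2 the meningeal call (0.494).

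**Figure D2:**
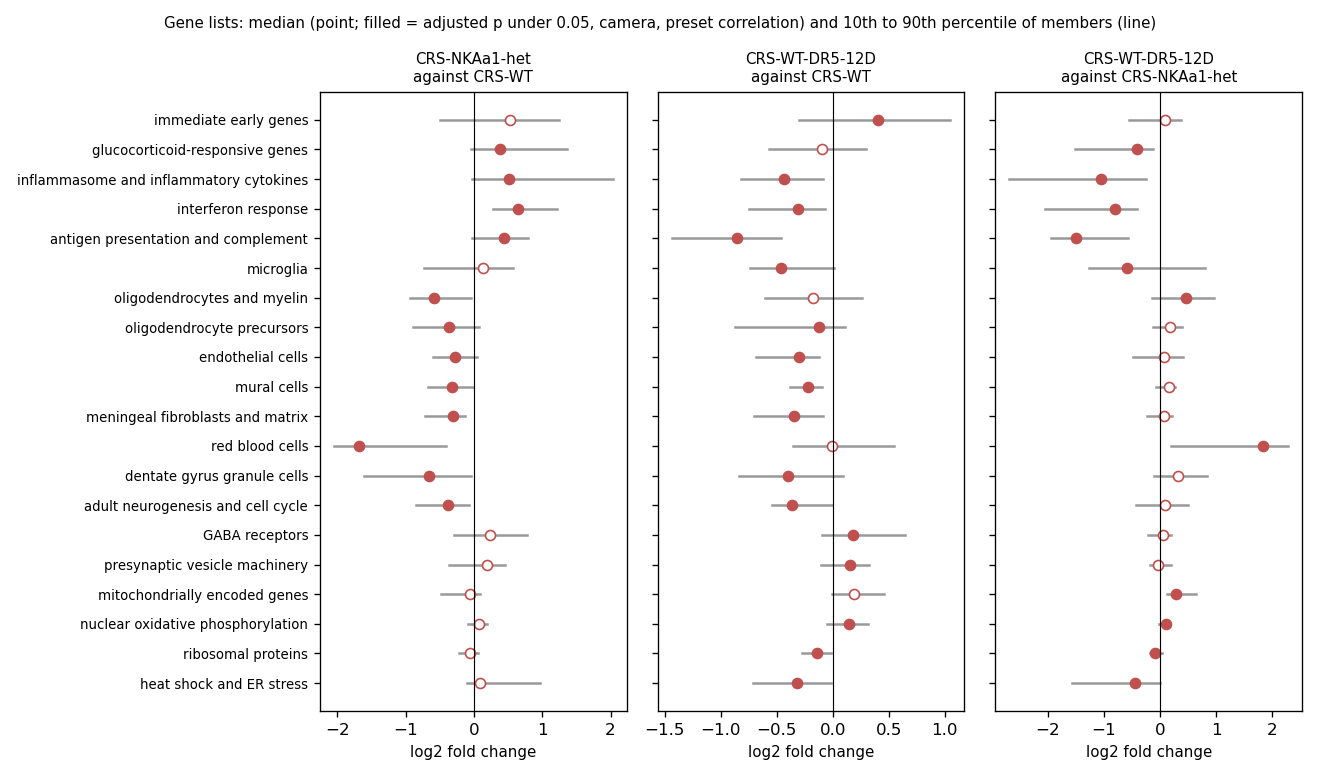
Median log2 fold change of the 20 gene lists called in any of the 3 comparisons, with lines from the 10th to the 90th percentile of the members and filled points for lists called by camera at a preset correlation of 0.01. In CRS-WT-DR5-12D against CRS-NKAα1+/- the antigen presentation and complement list lies at −1.5 and the red blood cell list at 1.84.

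The second comparison asks what differs between CRS-WT-DR5-12D and CRS-WT, libraries of the same genotype label. Here 5 genes rose and 0 fell, and Shc4 was the only protein-coding gene among them with a name other than a clone number. Shc4 rose from 6.40 ± 0.157 to 11 ± 0.224 FPKM (n = 3 each), a log2 fold change of 0.70 ± 0.078 (limma adjusted p 0.047). The other 4, named after their values were seen, were the antisense RNAs Gm43701, up by 2.69 ± 0.23 (adjusted p 0.0258), and Gm29629, which shares exon bases with Cdk18, up by 1.99 ± 0.19 (0.0401), 4930535I16Rik, up by 1.45 ± 0.15 (0.047), and the short miRNA model Gm24187, up by 2.64 ± 0.29 (0.047). Of the exon bases of 4930535I16Rik, 50.9% lie opposite exons of Rragc. All 5 were higher in 3 of 3 libraries than in any CRS-WT library. Genes short of the threshold with higher values were Teddm2 at 1.02 (adjusted p 0.0859), the isoprenoid enzyme Idi1 at 0.755 (0.0908), Usp46os2 at 0.82 (0.0908) and Cdk19os at 0.73 (0.0921). Those with lower values were the Fc receptor Fcgr3 at −1.17, the lysosomal protease Ctsh at −1.08 and Gpr17 at −1.03 (0.0811 each), Pla1a at −0.93 and the ER stress gene Creld2 at −0.65 (0.0859 each). At an unadjusted p under 0.05 there were 2314 genes, and in 22.8% of genes the groups did not overlap, where chance gives 10% on average. Limma called 0 genes without CRS-WT replicate 1 or any 1 of the 3 CRS-WT-DR5-12D replicates (1582, 1658, 1980 and 2362 at an unadjusted p under 0.05), 2 without CRS-WT replicate 2 or 3, 21 and 19 without CRS-NKAα1+/- replicate 1 or 2, and 6, 1 of them shared, without the 3 samples with lower dentate gyrus transcripts. It called 0 with no filter (3369 at an unadjusted p under 0.05) and 0 with voom (2439), and 41 with 2 groups only in the fit. After rescaling to TPM it called 28 higher and 947 lower, where the median of all genes moved from 0.0071 to −0.33.

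Immune and protein-folding lists were lower in CRS-WT-DR5-12D than in CRS-WT as sets, with 0 members past the threshold over all genes. Antigen presentation and complement genes had a median of −0.86, with 17 of 17 lower and 11 past the threshold adjusted over the list alone (camera adjusted p 2.34e-11; adjusted p = 0.672 with an estimated correlation). C1qa was at −1.16 ± 0.18, from 126 ± 19 to 56.1 ± 7.79 FPKM, C1qb at −1.03, C1qc at −0.93 and the class I molecule H2-D1 at −1.53. Microglia genes had a median of −0.47, with 14 of 16 lower and 9 past the threshold adjusted over the list alone (camera adjusted p 3.59e-08; adjusted p = 0.672 with an estimated correlation). They include the protease Ctss at −1.01, the growth factor receptor Csf1r at −0.715, Trem2 at −0.70 and Olfml3 at −0.53. Inflammasome and cytokine genes had a median of −0.43, with 21 of 22 lower and 1 past the threshold adjusted over the list alone (camera adjusted p 4.65e-06; adjusted p = 0.672 with an estimated correlation), the NF-kappaB subunit Nfkb2 at −0.73, beside the chemokine Ccl5 at −1.83, Casp1 at −0.48 and Myd88 at −0.36. Interferon-response genes had a median of −0.31 with 18 of 18 lower and 0 past the threshold adjusted over the list alone (camera adjusted p 0.00292; adjusted p = 0.707 with an estimated correlation). Among them were Gbp3 at −0.81, Gbp7 at −0.37, Ifit1 at −0.445 and Bst2 at −1.36. Bst2 had 933 fragments in CRS-WT replicate 1, 179 and 192 in replicates 2 and 3, and 76 to 143 in CRS-WT-DR5-12D. Its value thus rests largely on CRS-WT replicate 1. Heat shock and ER stress genes had a median of −0.32, with 19 of 20 lower and 10 past the threshold adjusted over the list alone (camera adjusted p 1.31e-07; adjusted p = 0.672 with an estimated correlation). Members include Creld2 at −0.65, Sdf2l1 at −0.93 and the chaperones Hspa5 at −0.70 and Calr at −0.50. After rescaling to TPM the inflammasome and interferon calls were lost (adjusted p 0.0533 and 0.128), with medians of −0.89 and −0.70.

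Vascular and precursor lists were also lower in CRS-WT-DR5-12D than in CRS-WT, and synaptic and respiratory lists were higher by small amounts. Endothelial genes had a median of −0.305, with 12 of 12 lower and 6 past the threshold adjusted over the list alone (camera adjusted p 7.77e-06; adjusted p = 0.672 with an estimated correlation). Examples are Vwf at −0.72, Ly6c1 at −0.72, Slco1a4 at −0.405 and Esam at −0.37. Mural genes had a median of −0.22 with 1 of 9 lower adjusted over the list alone (camera adjusted p 0.0192; adjusted p = 0.672 with an estimated correlation), Rgs5 at −0.66, beside Vtn at −0.31, Kcnj8 at −0.23 and Abcc9 at −0.19. Precursor genes had a median of −0.12, with 4 of 10 lower and 1 higher adjusted over the list alone (camera adjusted p 0.0458; adjusted p = 0.672 with an estimated correlation), Gpr17 at −1.03, Bmp4 at −0.86 and Neu4 at −0.33, but the receptor Pdgfra at 0.31. Ribosomal protein genes had a median of −0.14 with 2 of 32 lower adjusted over the list alone (camera adjusted p 3.36e-05; adjusted p = 0.694 with an estimated correlation), Rpl18 at −0.50 and Rpl11 at −0.35, beside Rpl5 at −0.275 and Rps3 at −0.25. Nuclear genes of oxidative phosphorylation had a median of 0.14 with 26 of 31 higher and 0 past the threshold adjusted over the list alone (camera adjusted p 0.00313; adjusted p = 0.726 with an estimated correlation), Cox7a2 at 0.52, Ndufb4 at 0.35 and Ndufs5 at 0.295 but Ndufb7 at −0.23. Under TPM the median was −0.225. The mural call was lost without CRS-WT replicate 2 or CRS-WT-DR5-12D replicate 1 (adjusted p 0.0506 and 0.258), and the precursor call without CRS-WT replicate 1, CRS-NKAα1+/- replicate 2 or CRS-WT-DR5-12D replicate 1 (0.12, 0.0599 and 0.155). The ribosomal call was lost without CRS-WT replicate 1 (0.12) and the respiratory call without CRS-WT-DR5-12D replicate 3 (0.0659). TPM ended the mural, precursor and respiratory calls (0.195, 0.128 and 0.484). The precursor call was also lost with a pseudocount of 0.1, a mean FPKM of at least 2, median-of-ratios scaling, 2 groups only in the fit, array weights and the replicate block (0.0603, 0.176, 0.0532, 0.0598, 0.116 and 0.0598).

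The mural and precursor lists also moved with CRS-WT-DR5-12D replicate 1, the sample of that group with lower dentate gyrus transcripts. Without it their medians were −0.079 and −0.0135. Without all 3 such samples both calls were lost (adjusted p 0.146 and 0.193), as they were with the dentate gyrus covariate (0.109 and 0.294). The first residual component as covariate also ended the precursor call (0.0686). The precursor median was −0.26 without CRS-WT replicate 2 and −0.205 without CRS-WT-DR5-12D replicate 3. The respiratory median was 0.084 without CRS-WT-DR5-12D replicate 3, and the ribosomal median was −0.036 without CRS-WT replicate 1.

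The remaining called lists of CRS-WT-DR5-12D against CRS-WT moved with the same sample. Immediate early genes had a median of 0.40 with 17 of 23 higher and 0 past the threshold adjusted over the list alone (camera adjusted p 0.0395; adjusted p = 0.672 with an estimated correlation). They include Dusp1 at 1.06, Nr4a1 at 1.07, Junb at 0.71 and Sik1 at 0.34. The list mean was 4.04 in CRS-WT-DR5-12D replicate 1 and 3.18 and 3.24 in replicates 2 and 3, beside 2.87 to 3.29 in CRS-WT. In CRS-NKAα1+/- against CRS-WT the same list had a median of 0.535, also with 17 of 23 higher, and was not called (camera adjusted p 0.0688). GABA receptor genes had a median of 0.18 and presynaptic vesicle genes of 0.16, with 11 of 14 and 16 of 22 higher and 0 past the threshold adjusted over the list alone (camera adjusted p 0.0395 and 0.0477; adjusted p = 0.672 for both with an estimated correlation). Among them were Gabrb2 at 0.53, Gabrg1 at 0.27, Gabrd at 0.73 and Gabra3 at 0.69, and Rab3a at 0.215, Syt1 at 0.26, Vamp2 at 0.21 and Syn1 at 0.30. Under TPM the medians of the lists were −0.18 and −0.20, beside −0.33 for all genes. Granule cell, neurogenesis and meningeal genes had medians of −0.40, −0.37 and −0.35, with 14 of 16, 9 of 10 and 11 of 11 lower and 0 past the threshold adjusted over the list alone (camera adjusted p 0.0458, 0.0458 and 0.0395; adjusted p = 0.694, 0.672 and 0.726 with an estimated correlation). The granule cell list mean was 1.58 in CRS-WT-DR5-12D replicate 1 and 2.61 and 2.51 in replicates 2 and 3. Examples are Maml2 at −0.62, Npnt at −0.45, Sipa1l2 at −0.43 and Calb1 at −0.23, Mki67 at −0.53, Sox4 at −0.32, Sox11 at −0.38 and Dcx at 0.39, and Col1a1 at −1.06, Col3a1 at −0.70, Ogn at −0.63 and Col1a2 at −0.40. Without CRS-WT-DR5-12D replicate 1 the calls of the immediate early, GABA receptor, presynaptic, neurogenesis and meningeal lists were lost (adjusted p 0.277, 0.205, 0.354, 0.286 and 0.905), as was that of the granule cell list, with a median of −0.061 (0.554). They were also lost without CRS-WT replicate 1 for the GABA receptor, presynaptic, neurogenesis and meningeal lists (0.122, 0.195, 0.177 and 0.223), and without CRS-WT replicate 2 or 3 for the immediate early list (0.148 and 0.0539). Further omissions that ended a call were CRS-WT-DR5-12D replicate 2 for GABA receptors (0.0731), CRS-NKAα1+/- replicate 1 or 2 for presynaptic genes (0.0544 and 0.0599), and CRS-NKAα1+/- replicate 2 or CRS-WT-DR5-12D replicate 3 for neurogenesis (0.0558 and 0.0501). The granule cell call was also lost without CRS-WT replicate 1 or 2 or CRS-WT-DR5-12D replicate 3 (0.131, 0.0761 and 0.0501).

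Other settings ended these calls of CRS-WT-DR5-12D against CRS-WT as well. TPM ended the presynaptic, granule cell, neurogenesis and meningeal calls (adjusted p 0.706, 0.929, 0.929 and 0.929), median-of-ratios scaling the same 4 (0.0532, 0.0588, 0.0588 and 0.0532) and array weights these (0.191, 0.175, 0.175 and 0.399) and the GABA receptor call (0.0755). The presynaptic call was also lost with a pseudocount of 0.1, a mean FPKM of at least 2, quantile scaling, 2 groups only in the fit, no trend and voom (0.0559, 0.0617, 0.147, 0.0501, 0.0537 and 0.0556). A pseudocount of 0.1 ended the granule cell call (0.0598), a mean FPKM of at least 2 the GABA receptor and meningeal calls (0.112 and 0.444), and 2 groups only in the fit the meningeal call (0.0501). With the dentate gyrus covariate all 6 calls, the immediate early one included, were lost (0.166, 0.0648, 0.432, 0.889, 0.628 and 0.938 for the immediate early, GABA receptor, presynaptic, granule cell, neurogenesis and meningeal lists). The loss of the granule cell call was fixed in advance, because the covariate is the mean of that list. Without the 3 samples with lower dentate gyrus transcripts all but the immediate early call were lost (0.0729, 0.228, 0.246, 0.296 and 0.836 in that order). Without CRS-WT-DR5-12D replicate 1 the medians of the immediate early, GABA receptor, presynaptic, neurogenesis and meningeal lists were 0.18, 0.10, 0.075, −0.175 and −0.0088. The immediate early and GABA receptor medians were 0.62 and 0.28 without CRS-WT-DR5-12D replicate 3, the presynaptic median 0.25 without replicate 2, and the meningeal median −0.19 without CRS-WT replicate 1.

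The third comparison, CRS-WT-DR5-12D against CRS-NKAα1+/-, differs in both genotype and treatment and held most of the calls. Of 17753 genes 89 fell and 2 rose. Of the 89, 5 are on the antigen presentation and complement list, 5 on the microglia list, 4 on the heat shock list and 3 each on the inflammasome and interferon lists, and 67 are on none of the 40 lists. The acute-phase and myeloid genes S100a9, Saa3, Lcn2 and S100a8 fell by 4.57 ± 0.62, 4.55 ± 0.66, 4.14 ± 0.68 and 4.11 ± 0.61 on the log2 scale (limma adjusted p 0.0275, 0.0334, 0.0457 and 0.0352). Mean S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) was 57.0 ± 48.5 FPKM in CRS-NKAα1+/-, 0.884 ± 0.260 in CRS-WT-DR5-12D and 11.8 ± 6.60 in CRS-WT (SD, n = 3 each). The chemokines Cxcl1, Ccl12 and Cxcl2 fell by 4.03 ± 0.46, 3.84 ± 0.51 and 2.79 ± 0.38 (adjusted p 0.0173, 0.0269 and 0.0276), and the cytokine Il1b fell by 3.65 ± 0.58 (0.0423). Mean Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115) was 26.7 ± 17.0 FPKM in CRS-NKAα1+/-, 0.481 ± 0.153 in CRS-WT-DR5-12D and 1.39 ± 1.07 in CRS-WT. The adhesion molecule Icam1 fell by 3.40 ± 0.39 (0.0173) and the fatty acid receptor Gpr84 by 2.87 ± 0.42 (0.0343), with 11.7% and 39.5% of their exon bases shared with other genes. Srgn, named here after its values were seen, had the smallest adjusted p (0.00264) and fell by 1.60 ± 0.10, to 3.39 ± 0.515 FPKM. Opalin, a myelin protein (ENSMUSG00000050121, chromosome 19, 41061710 to 41077113), rose by 1.54 ± 0.21 (adjusted p 0.0287), from 4.97 ± 1.31 to 16.6 ± 5.39 FPKM, and the other gene that rose was Gm2061, by 0.60 (0.0446), named after its values were seen. Short of the threshold with higher values were Gkn3 at 1.47 (adjusted p 0.0558), the globin Hbb-bt at 2.46 (0.0647), AI849053 at 0.71 (0.0697) and the microglial receptor Gpr34 at 0.89 (0.0824).

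**Figure D3:**
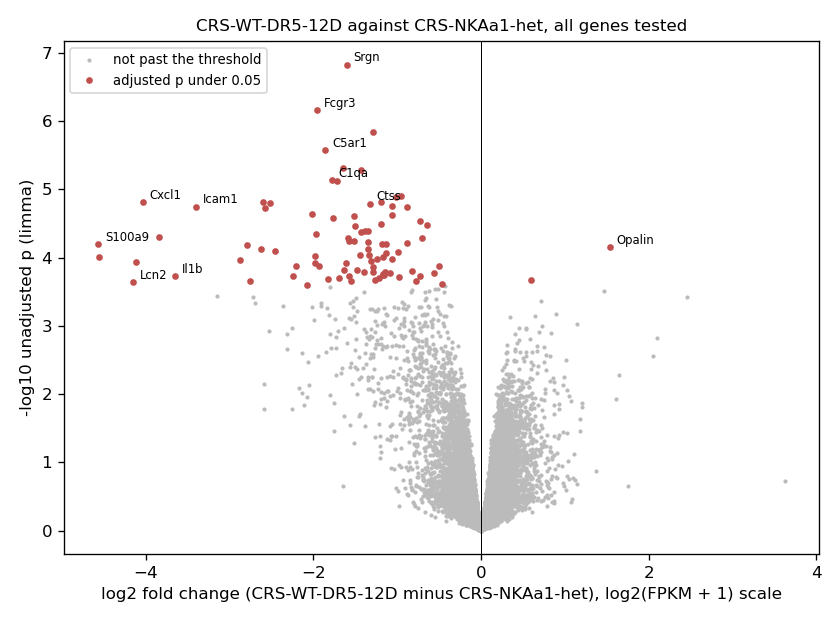
Log2 fold change of each of 17753 genes in CRS-WT-DR5-12D against CRS-NKAα1+/- on the horizontal axis and −log10 of the unadjusted p on the vertical axis, with red points for an adjusted p under 0.05. Of the 91 red points 89 lie on the lower side, with S100a9 at −4.57.

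At an unadjusted p under 0.05 there were 1568 genes in CRS-WT-DR5-12D against CRS-NKAα1+/-, and in 12.5% of genes the groups did not overlap, where chance gives 10% on average. The number of calls was 1 without CRS-WT-DR5-12D replicate 2, which left Srgn alone, 12 and 8 without replicates 1 and 3, 31, 32 and 25 without CRS-WT replicates 1 to 3, and 194 and 58 without CRS-NKAα1+/- replicates 1 and 3. Srgn was called in all 9 omissions of 1 library, Fcgr3, Spint1, C5ar1 and Ly6a in 8, C1qa, C1qb and Ctss in 7, Cxcl1 and Icam1 in 6, S100a9 and Saa3 in 2, and Il1b and Lcn2 in 1. Spint1 and Ly6a were named after their values were seen. The count of calls was 5 with 2 groups only in the fit and 30 with no filter. Without the 3 samples with lower dentate gyrus transcripts CRS-NKAα1+/- replicate 3 is alone in its group, so no count is given. A moderated F-test across the 3 groups called 48 genes, 36 of which were among the 91, and 7 of which were called in no pair of groups. Its count without CRS-WT replicates 1 to 3 was 3, 10 and 5, without CRS-NKAα1+/- replicate 1 it was 151, and without CRS-WT-DR5-12D replicates 1 to 3 it was 9, 1 and 1.

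By list, immune and stress genes were lower in CRS-WT-DR5-12D than in CRS-NKAα1+/- as sets by camera at its preset correlation, although few members fell over all genes and no list was called with an estimated correlation. In the inflammasome and cytokine list 3 of 22 genes fell over all genes tested, Il1b, Nfkb2 by 1.06 and Myd88 by 0.71, and 17 adjusted over the list alone, with Ccl5 at −3.15 (median −1.05, camera adjusted p 4.69e-21; adjusted p = 0.181 with an estimated correlation). In the interferon-response list 3 of 18 fell over all genes, Ifit1 by 1.58, Gbp3 by 1.39 and Gbp7 at −0.725, and 17 adjusted over the list alone, with Irf9 at −0.83 (median −0.80, camera adjusted p 6.25e-19; adjusted p = 0.277 with an estimated correlation). In the antigen presentation and complement list 5 of 17 fell over all genes and 14 adjusted over the list alone (median −1.5, camera adjusted p 4.69e-21; adjusted p = 0.181 with an estimated correlation). The complement chains C1qa, C1qb and C1qc fell by 1.78 ± 0.18, 1.64 ± 0.16 and 1.5 ± 0.19 (adjusted p 0.0166, 0.0157 and 0.0229), and the class I molecule H2-D1, whose fragments may be shared with its paralogs, fell by 1.97 ± 0.26 (0.0257). C1qa went from 197 ± 45.9 to 56.1 ± 7.79 FPKM, with 126 ± 19 in CRS-WT. In the glucocorticoid list 1 of 20 fell over all genes, Lcn2, which inflammation also induces, and 10 adjusted over the list alone (median −0.41, camera adjusted p 1.92e-10; adjusted p = 0.181 with an estimated correlation), with Plin4 at −1.24, Nfkbia at −1.48 and Cdkn1a at −1.85. In the heat shock and ER stress list 4 of 20 fell over all genes, Creld2 by 0.72, Sdf2l1 by 1.35, Hspa1a by 1.61 and Hspb1 by 1.83, and 12 adjusted over the list alone (median −0.45, camera adjusted p 3.9e-15; adjusted p = 0.181 with an estimated correlation). Hspa1a is a near copy of Hspa1b and overlaps Gm20481 in 19% of its exon bases. Fry also called the glucocorticoid, inflammasome, antigen presentation and heat shock lists, at an adjusted p of 0.0187 each, but not the interferon list (0.0558). None of these members kept its call without CRS-WT-DR5-12D replicate 2, where limma called 1 gene, Srgn.

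Microglia genes moved in both directions in CRS-WT-DR5-12D against CRS-NKAα1+/-. Of 16 members 5 fell over all genes and 9 adjusted over the list alone, while 3 were higher adjusted over the list alone (median −0.58, camera adjusted p 2.68e-08; adjusted p = 0.422 with an estimated correlation). Ctss fell by 1.33 ± 0.15 (adjusted p 0.0173), from 129 ± 17.0 to 51.3 ± 10 FPKM, the signalling adaptor Tyrobp by 1.19 (0.0224), Olfml3 by 0.88 (0.0173), the integrin Itgam by 1.17 (0.0334) and Tmem119 by 1.16 (0.0423). Tmem119 was named after its values were seen. The 3 that were higher, chosen after their values were seen, were the receptors Gpr34 at 0.89, Siglech at 0.83 and P2ry12 at 0.78. Against CRS-WT the same 3 were at −0.93, −0.77 and −0.70 in CRS-NKAα1+/-, past the threshold adjusted over the list alone, and at −0.039, 0.061 and 0.075 in CRS-WT-DR5-12D, not past it. Of the exon bases of Itgam 68.7% also belong to Gm49368. The microglia list against CRS-WT in CRS-NKAα1+/- was not called, with 3 higher and 4 lower adjusted over the list alone (median 0.13, adjusted p 0.598). Without CRS-WT-DR5-12D replicate 2 none of the 5 stayed called, where limma called 1 gene in all.

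Myelin, red blood cell and mitochondrial lists were higher in CRS-WT-DR5-12D than in CRS-NKAα1+/-. In the oligodendrocyte list 1 of 18 genes rose over all genes, Opalin, and adjusted over the list alone 2 rose and 1 fell (median 0.465, camera adjusted p 9.98e-06; adjusted p = 0.741 with an estimated correlation), with Mog at 0.93 and the lipid carrier Apod at −1.49. Of 6 red blood cell genes 0 passed over all genes and 4 were higher adjusted over the list alone (median 1.84, camera adjusted p 2.07e-06; adjusted p = 0.277 with an estimated correlation), Hbb-bt at 2.46, Hbb-bs at 2.10, Hba-a1 at 2.05 and Hba-a2 at 1.62. Of 13 mitochondrially encoded genes 13 were higher and 0 passed adjusted over the list alone (median 0.29, camera adjusted p 0.00818; adjusted p = 0.741 with an estimated correlation). Among them were mt-Atp8 at 0.88, mt-Nd4l at 0.67, mt-Nd1 at 0.38 and mt-Nd3 at 0.29. In CRS-WT-DR5-12D replicates 1 to 3 mt-Atp8 had 30, 7 and 9 fragments and mt-Nd4l 286, 94 and 45. In CRS-NKAα1+/- they had 2 to 8 and 61 to 81. The list mean was 9.64, 9.21 and 8.70 in CRS-WT-DR5-12D replicates 1 to 3, beside 8.815 to 8.88 in CRS-NKAα1+/-. Nuclear genes of oxidative phosphorylation had a median of 0.11 with 0 past the threshold adjusted over the list alone (camera adjusted p 0.00881; adjusted p = 0.848 with an estimated correlation), Cox7b at 0.26, Cox7a2 at 0.23, Ndufs8 at 0.18 and Cox6b1 at 0.17. Ribosomal protein genes were lower by a median of −0.080 with 0 past the threshold adjusted over the list alone (camera adjusted p 0.0187; adjusted p = 0.848 with an estimated correlation), Rplp0 at −0.24, Rpl18 at −0.21, Rps20 at −0.16 and Rps21 at −0.14. Under TPM their median was 0.027, beside 0.10 for all genes. The endothelial list was not called (adjusted p 0.837), though Ly6c1 fell by 1.08 (adjusted p 0.0416), with Itm2a at 0.975, Flt1 at 0.31 and Vwf at −0.47. Omissions that ended a call were CRS-NKAα1+/- replicate 3 or CRS-WT-DR5-12D replicate 1 for mitochondrial genes (adjusted p 0.0787 and 0.401). For nuclear respiratory genes they were CRS-NKAα1+/- replicate 1, with a median of 0.0044, or CRS-WT-DR5-12D replicate 3 (0.906 and 0.23), and for ribosomal genes CRS-NKAα1+/- replicate 2 or 3 or CRS-WT-DR5-12D replicate 1 (0.634, 0.216 and 0.0974). Array weights ended the mitochondrial call (0.147) and TPM the ribosomal call (0.45), as did the first residual component as covariate (0.0647). The mitochondrial median was 0.20 without the 3 samples with lower dentate gyrus transcripts, which leaves CRS-NKAα1+/- replicate 3 alone in its group. The nuclear respiratory call was lost with the dentate gyrus covariate (median 0.031, camera adjusted p 0.475), and without the 3 samples the median of that list was −0.059. The mitochondrial median was 0.084 and 0.49 without CRS-WT-DR5-12D replicates 1 and 3, and the myelin median 0.26 without replicate 2. The nuclear respiratory median was 0.20 without CRS-NKAα1+/- replicate 3 and 0.062 without CRS-WT-DR5-12D replicate 3, and the ribosomal median −0.15 and −0.03 without CRS-NKAα1+/- replicates 1 and 2. Without CRS-WT-DR5-12D replicate 2 neither Opalin nor Ly6c1 was called.

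The changes of the 2 groups against CRS-WT were related across genes, with a Pearson r of 0.540 and the same sign in 74.1% of 17753 genes. Genes are not independent replicates, and both comparisons use the same 3 CRS-WT libraries. In 100 simulations of 3 unchanged groups with these shared controls and genes drawn as independent, r was 0.463 to 0.534 with a mean of 0.499. There the sign was the same in 66.6% of genes on average, and the covariance was 0.0164 to 0.0199 where the data gave 0.0507. Of the 840 ways to regroup the 9 libraries into controls and 2 other groups, which keep the relation between genes, 72 gave a covariance as large. Gm43701 and Shc4 rose in both comparisons, and 0 genes fell in both by limma. Without the 3 samples with lower dentate gyrus transcripts, which leaves CRS-NKAα1+/- replicate 3 alone in its group, r was 0.349. Of the 60 regroupings of the other 6 libraries 27 gave an r as large. The 3 control libraries do not divide evenly, and they were not split to give each comparison its own.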

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

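The settings without the 3 samples with lower dentate gyrus transcripts, with the dentate gyrus covariate, with voom and with the first residual component were chosen after seeing the data. Counts below are of genes called in CRS-NKAα1+/- against CRS-WT, CRS-WT-DR5-12D against CRS-WT, CRS-WT-DR5-12D against CRS-NKAα1+/- and the F-test, with 4, 5, 91 and 48 as first reported. All 33 called values of named genes kept their direction in every alternative, 39 of 189 named values kept direction and side of the threshold throughout, and 18 of 39 list calls held under every planned scaling, filter and omission. At these depths and 3 libraries per group, 47% to 58% of 2-fold changes were found in simulations with genes drawn as independent. Except where said, the cause was not tested.

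With no filter the counts were 0, 0, 30 and 6 by limma (3538 and 3369 genes at an unadjusted p under 0.05 for the first 2), with more genes tested. Rescaling to TPM gave 7451, 975, 68 and 1751. There the miRNA model Gm23935, of 57 bases, took 4.67% to 37.9% of the FPKM sum and so moved all other genes. Its share was 4.95%, 4.67% and 19.3% in CRS-WT replicates 1 to 3. It was 37.9%, 37.6% and 28.6% in CRS-NKAα1+/- and 33.5%, 26.5% and 31.6% in CRS-WT-DR5-12D. The share was thus lower in each CRS-WT library than in any other library, and the cause was not tested. A pseudocount of 0.1 gave 100 in the F-test. Array weights gave 104, 50, 126 and 210. For CRS-WT-DR5-12D against CRS-WT, median-of-ratios scaling, no trend and robust fitting each gave 2, and 2 groups only in the fit gave 41, beside 5 for CRS-WT-DR5-12D against CRS-NKAα1+/-. Deviations from the group means had r of −0.35 to 0.497 over 9 pairs of libraries with the same replicate number, 2 of them above 0.1. A pair of different number reached 0.505, and the sizes followed which samples had lower dentate gyrus transcripts. Pairing was therefore neither shown nor excluded. Blocking on the replicate numbers gave 0, 0, 40 and 7 (2547 and 2217 at an unadjusted p under 0.05 for the first 2). Omission of 1 library gave 0 to 25, 0 to 21, 1 to 194 and 1 to 151, and 36 to 49 called lists, with fewer samples. The estimated correlation called 0 lists and fry 4, of 39 at the preset correlation.

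Without the 3 samples with lower dentate gyrus transcripts the counts were 41 in CRS-NKAα1+/- against CRS-WT and 86 in the F-test, and the r between the changes against CRS-WT was 0.349. That omission leaves CRS-NKAα1+/- replicate 3 alone in its group, so the spread within that group cannot be measured. These counts therefore cannot show that more genes changed than first reported, and no conclusion is drawn from them. The dentate gyrus covariate gave 1 and 19 against CRS-WT and an r of 0.461. Voom gave 2 and 0 against CRS-WT (2507 and 2439 at an unadjusted p under 0.05) and an r of 0.52. Some list medians were larger in size with voom, which does not add 1 to FPKM, than those first reported. Inflammasome and interferon genes stood at −1.88 and −1.41 in CRS-WT-DR5-12D against CRS-NKAα1+/- and at −0.80 and −0.54 in CRS-WT-DR5-12D against CRS-WT. Others moved little, such as microglia genes in CRS-WT-DR5-12D against CRS-NKAα1+/- (−0.612 beside −0.582). The first residual component gave 2099, 742, 493 and 1938. By construction that covariate leaves the fold changes as they are and shrinks their error, so its p values are too small.

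In CRS-NKAα1+/- against CRS-WT, TPM turned the meningeal list, as tested against other genes, with a median of −0.753, Myd88 (−0.0377) and Dcx (−0.0103). The dentate gyrus covariate turned the meningeal (0.254) and neurogenesis (0.107) lists, Atp1b1 (0.115), Ogn (0.116), Fmod (0.286) and Dcx (−0.0622). Without the 3 samples Atp1b1 (0.0844) turned. In CRS-WT-DR5-12D against CRS-WT, TPM turned Atp1b1 (−0.371), Rab3a (−0.157), Syt1 (−0.113), Vamp2 (−0.163), Syn1 (−0.0675), Ndufb4 (−0.0184) and Ndufs5 (−0.0745), where the median of all genes lay at −0.327. Atp1b1 also turned under median-of-ratios (−0.0147) and quantile scaling (−0.0186) and without CRS-WT replicate 1 (−0.0734) or CRS-WT-DR5-12D replicate 2 (−0.0783) or 3 (−0.0475), with −0.0783 to 0.131 over the omissions. Col1a2 turned without CRS-WT replicate 1 (0.0307), with −0.642 to 0.0307 over the omissions. In CRS-WT-DR5-12D against CRS-NKAα1+/-, the nuclear oxidative phosphorylation list turned without the 3 samples to a median of −0.0586, with CRS-NKAα1+/- replicate 3 alone in its group. Without CRS-NKAα1+/- replicate 1 its median was 0.00436 and the direction of its test turned; the omissions gave 0.00436 to 0.198. Omission of the 3 samples also turned Ndufs8 (−0.00308) and Cox7a2 (−0.0376).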

Other observations

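The tests of the dentate gyrus share, of blood, of microglia by the count of markers that were higher, of sequencing depth, of shared controls by regrouping and of the covariance after removal of the GC trend were chosen only after the results were seen. The other tests were written before. Lists not called in any comparison are given first, with medians for CRS-NKAα1+/- against CRS-WT, CRS-WT-DR5-12D against CRS-WT and CRS-WT-DR5-12D against CRS-NKAα1+/- in that order. Stress hormone and monoamine receptors had medians of −0.095, 0.014 and 0.11 (camera adjusted p 0.811, 0.688 and 0.522), and ion transporters and calcium pumps −0.033, 0.087 and 0.034 (0.911, 0.321 and 0.522). For Na,K-ATPase subunits the other medians were 0.053 and 0.070 (0.875 and 0.928). Glutamate receptors had medians of −0.0013, 0.033 and 0.052 (0.687, 0.716 and 0.442) and neurotrophic and neuropeptide genes 0.18, 0.18 and −0.17 (0.108, 0.402 and 0.492). Astrocyte genes stood at −0.092, −0.073 and 0.016 (0.182, 0.0594 and 0.837), blood-brain barrier genes at −0.135, −0.081 and 0.041 (0.0722, 0.0697 and 0.837), perivascular macrophage genes, 2 measured, at 0.34, 0.041 and −0.30 (0.25, 0.942 and 0.346) and lymphocyte genes, 5 measured, at 0.17, −0.46 and −0.55 (0.644, 0.0857 and 0.293). Nuclear long noncoding RNAs stood at 0.14, 0.076 and −0.145 (0.307, 0.942 and 0.264) and sex-linked genes at 0.017, 0.086 and 0.033 (0.899, 0.716 and 0.837), with the Y-linked Ddx3y at 6.32 to 8.93 FPKM and Xist at 0.0128 to 0.441 FPKM in the 9 libraries.

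Region and neuron lists were also not called. Pan-neuronal genes had medians of 0.18, 0.22 and 0.036 (camera adjusted p 0.224, 0.0658 and 0.686) and interneuron genes −0.038, 0.14 and 0.16 (0.911, 0.128 and 0.132). CA1 genes stood at 0.013, 0.12 and 0.13 (0.852, 0.597 and 0.502), CA2 genes at −0.12, −0.026 and 0.059 (0.48, 0.765 and 0.73) and CA3 genes at −0.31, −0.19 and 0.10 (0.0564, 0.128 and 0.73). Ventral hippocampus markers stood at −0.34, −0.065 and 0.16 (0.0681, 0.459 and 0.346), with list means of 2.55 to 2.61 in the 3 samples with lower dentate gyrus transcripts and 3.15 to 3.46 in the other 6. Genes of thalamus, striatum, hypothalamus and amygdala stood at 0.099, 0.024 and −0.025 (0.894, 0.942 and 0.837), choroid plexus genes, 4 measured, at −0.54, −0.43 and 0.056 (0.094, 0.1 and 0.837) and ependymal genes at −0.20, −0.27 and 0.17 (0.21, 0.244 and 0.837).

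Some lists called in 1 comparison were not called in another, and each is given with its median and camera adjusted p. In CRS-NKAα1+/- against CRS-WT these were the heat shock (0.090, 0.0535), ribosomal (−0.052, 0.0538), mitochondrial (−0.051, 0.531), nuclear respiratory (0.068, 0.531), microglia (0.13, 0.598), GABA receptor (0.23, 0.224) and presynaptic (0.19, 0.117) lists, and immediate early genes (0.535, 0.0688). In CRS-WT-DR5-12D against CRS-WT they were the myelin (−0.17, 0.174), red blood cell (−0.011, 0.939), glucocorticoid (−0.096, 0.251) and mitochondrial (0.19, 0.0857) lists. In CRS-WT-DR5-12D against CRS-NKAα1+/- they were the immediate early (0.085, 0.837), granule cell (0.32, 0.0753), neurogenesis (0.098, 0.837), GABA receptor (0.051, 0.502) and presynaptic (−0.029, 0.837) lists. The precursor (0.17, 0.061), endothelial (0.081, 0.837), mural (0.166, 0.53) and meningeal (0.080, 0.837) lists were also not called there.

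Median, mean and test differed in sign in 7, 2 and 7 lists of the 3 comparisons. In the first these were the Na,K-ATPase, ion transporter, lymphocyte, interneuron, CA1, neighbouring-region and glutamate receptor lists, and in the second the red blood cell and long noncoding lists. In the third they were the Na,K-ATPase, immediate early, astrocyte, endothelial, choroid plexus, neighbouring-region and presynaptic lists.

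The genes lower in CRS-WT-DR5-12D than in CRS-NKAα1+/- were set against what the tissue held. With the mean of the 16 dentate gyrus genes as a covariate 62 of the 89 genes that fell stayed called and their median moved from −1.44 to −1.43, which argues against the share of dentate gyrus as the whole cause. More blood in the CRS-NKAα1+/- tissue would raise globin transcripts there, but the red blood cell list had a median of 1.84, with 6 of 6 genes higher in CRS-WT-DR5-12D, which argues against it. A lower share of microglia would lower all markers, but 3 of 16 were higher adjusted over the list alone, Gpr34, Siglech and P2ry12. A lower share alone does not account for these 3, but the bound of 3 was set after they were seen, so the test decides nothing further. The test written before the result was seen compared the medians of the inflammatory and microglia lists. It gave a difference of −0.465 with a 95% bootstrap interval of −1.7 to 0.185, with genes drawn as independent, and excluded nothing. The log2(FPKM + 1) scale shrinks changes of genes with low values, which can narrow such a difference. With voom the medians of the inflammatory and microglia lists were −1.88 and −0.612, and the test was not run on them. A lower share of microglia thus stays open. A difference in the state of microglia and other cells between the groups may remain, and genotype and DR5-12D, which change together here, stay open and untested.

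The 3 samples with lower dentate gyrus transcripts were set against depth, base composition and neighbouring tissue. Their depths do not set them apart, since 4 other libraries lie within their range, and removal of the trend on GC content and gene length in each library left 103% of the median difference of dentate gyrus genes (−0.839 before and −0.867 after), which argues against both. Cortical tissue stays open. Of 19 cortical layer markers listed, 18 were tested, and these 18 also had a mean of at least 0.5 FPKM in the other 6 libraries. Their median log2 difference was 0.0783, under the bound of 0.2 written in advance, but its bootstrap interval of −0.284 to 0.61 passes that bound. Of the 18, 9 were higher, and 7 were higher in each of the 3 than in each of the 6. Of genes chosen after their values were seen, Tbr1 was at 17.6 to 21.5 FPKM in the 3 and 4.08 to 6.34 in the other 6, Cux2 at 10.1 to 11.2 and 2.18 to 3.66 and Mef2c at 39.2 to 42.4 and 6.9 to 9.29. No biological explanation was tested, and 2 of these samples are in CRS-NKAα1+/-, 1 in CRS-WT-DR5-12D and 0 in CRS-WT.

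The genes changed alike in both groups against CRS-WT were set against technical explanations, and the tables argue against GC content as the whole cause, since 98.2% of the covariance was left after removal of its trend (95.6 to 99.3% without each library in turn) and 5 of the 9 calls against CRS-WT, just past the bound written before. The removal moved single fold changes by up to 1.44, and of the 4 calls on the genes called in both comparisons it ended those of Shc4 (0.745 ± 0.0778 to 0.721 ± 0.0832, adjusted p 0.0668, and 0.701 ± 0.0778 to 0.695 ± 0.0832, adjusted p 0.0725), mainly through a slightly larger error. Shared CRS-WT libraries stay open, since 72 of 840 regroupings of the 9 libraries (8.57%) gave a covariance as large as the real 0.0507, the highest with the 3 samples with lower dentate gyrus transcripts as controls (0.134); the bound written before, the highest of 100 simulated values (0.0199), drew genes as independent and is too narrow. Those 3 samples, all outside CRS-WT, stay open too, as without them the covariance was 0.0285 and 11 of 60 regroupings gave one as large. Antisense counting stays open, since 1208 antisense genes were higher by a median of 0.0931 relative to protein-coding genes of like expression. The interval of 0.0773 to 0.107 passes the bound of 0.1. The miRNA model Gm23935 also set CRS-WT apart, with 4.67% to 19.3% of the FPKM sum there and 26.5% to 37.9% in the other groups. Whether this bears on the shared changes was not tested.

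Other splits of the same libraries were counted. For each pair of groups the 10 splits are too few for a share under 0.05. In CRS-NKAα1+/- against CRS-WT 1 of 10 splits, the real one, called as many as 4 genes, and the highest other called 0; in CRS-WT-DR5-12D against CRS-WT it was also 1 of 10, with 5 genes and 0 in the highest other. In CRS-WT-DR5-12D against CRS-NKAα1+/- 2 of 10 called at least 91 genes, and the highest other, which put the 3 samples with lower dentate gyrus transcripts in 1 group, called 3452. In the F-test 6 of 100 splits called at least 48 genes, so chance is not excluded. The highest other called 2895, and all 5 other splits as large kept those 3 samples together, which points to a structure of the samples that the groups do not follow.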
